A study of Homo sapiens with 12 samples.

How the data were processed

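Per the labels, H9 cells were grown in mTeSR1 on Geltrex, seeded at 100% confluency on Matrigel in KSR-based medium with 50 ng/ml BMP4 changed every 24 h, and lysed for RNeasy Mini extraction. Libraries were made from 1 µg of total RNA with the TruSeq Stranded Total RNA LT kit. Per the submitters' processing notes, reads were aligned with STAR 2.4.2a, assigned to genes with featureCounts and normalized with DESeq2 1.15.3. The genome build, the annotation, and the strand and multimapping options were not given in the sources used here. The values deposited by the authors are DESeq2 size-factor normalized counts (signal) for 22546 gene names in 12 columns. Dividing each column by its step between neighbouring values recovered whole reads for 100% of values (within 0.01), and these reads fed the count models and depth figures. On them edgeR called 3561, 7230, 8439, 10720 and 12124 genes at 8, 16, 24, 48 and 72 h against 0 h.

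Column names were matched to the labels by time and replicate. The column headed 71 h was read as 72 h replicate 1, because the labels have 2 replicates at 72 h and none at 71 h. In gene names hyphens had been written as dots, and 2 names were repeated. Of the names, 20439 matched a current RefSeq symbol, 1397 a synonym and 710 neither, and 253 genes were 0 in every library. RefSeq served for symbols and gene classes only. Of 674 list members 9 were absent from the table (LNCPRESS1, CGB3, INSL4, PSG1, PSG3, PSG4, PSG5, PSG9 and XAGE3).

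Genes with a mean of at least 10 over the 12 libraries (16147) were tested on log2(value + 1) with limma 3.58.1 (lmFit, then eBayes with trend=TRUE). One fit held all 12 libraries with 1 mean per time point, 6 residual degrees of freedom and 5.79 prior degrees of freedom. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p below 0.05. Changes over the course were tested with the moderated F test of the 5 differences from 0 h. Transient genes were called higher at a time than at 0 h and lower at 72 h than at that time. Unchanged groups were simulated 20 times to find how many such genes arise with no effect.

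Gene lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. Exceptions were the list tests in the steps between samples, which were not in that plan, and the settings and tests stated below to have been added later. The 31 lists covered pluripotency, trophectoderm, trophoblast, keratins and junctions, amnion, mesoderm, endoderm, neural, endothelial and blood, fibroblast and matrix, 6 signalling pathways, DNA methylation, imprinting, cell cycle, stress, sterol, interferon, HLA, mesenchymal transition, immediate early, mitochondrial, histone, HOX and small nucleolar host genes. Each list with at least 5 tested members (30) was tested with limma camera at its preset inter-gene correlation of 0.01, adjusted over the lists of 1 comparison. The same test with an estimated correlation is printed beside it. The preset value assumes nearly independent genes, so a call that it alone supports is weak. Lists were tested in the same way in the steps between samples. All 117 list calls had a median, mean and test of 1 sign, and 10 were called with an estimated correlation too. Under 3 other scalings the sign of the median relative to all genes was kept in all 117. Scaling moves all genes nearly alike, so this sign could hardly turn and lends the calls no support. Counts of members come from the genome-wide adjustment, and counts adjusted over the list alone are given beside them where they differ. A member near 0 at the start passed the mean filter only if it was higher later, which favours rises in the lists. Some genes were in more than 1 list, such as TBX3 and DLX5 in both the BMP-SMAD and trophectoderm lists. Calls of such lists are not independent.

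Named genes follow 1 rule. They were 13 marker genes at every time, up to 4 called members of each list with the largest change and a mean of at least 50 in the higher group, the 6 largest rises and falls at 8, 24 and 72 h and the 4 largest in each step (mean of at least 100), and the 4 strongest transient genes per time. Some members that met the rule were left out of the text because their call was lost without 1 library.

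Folds are ratios of group means of the normalized counts. Log2 fold changes are differences of mean log2(value + 1), and for genes of low count they understate the ratio. Where 1 group was 0, the fold is given as a minimum, the mean of the other group over a floor of 3 counts in the group at 0, which was 0.898 at 0 h and 1.71 at 72 h. Where a group held 1 to 3 reads, the ratio of pooled reads is given with an exact 95% interval. Floors and intervals cover counting error only and not differences between cultures. Shares of reads carry Wilson 95% intervals.

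Several genes share sequence or overlap, and their values cannot be fully separated. These include TDGF1 and TDGF1P3, CUZD1 and FAM24B-CUZD1, HIST2H2AA3 and HIST2H2AA4, KRT17 and its pseudogenes, POU5F1 and NANOG and their pseudogenes, and the HLA and histone families. Ribosomal and signal recognition particle RNAs (RNA45S5, RN7SL1, RN7SL2) come from repeated loci. Antisense reads could not be examined because strand settings were not stated.

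The methods were tested on simulated data in which 200 of 16147 genes were changed between 0 and 8 h. At log2 fold changes of 0.5, 1 and 2, limma found 32.8%, 71.6% and 93.9% of them, with 6 false calls of 138, and called 0 genes at 72 h, where nothing was changed. In the same data edgeR found 40.3%, 77.6% and 98.5% with 15 false calls of 159, and DESeq2 38.8%, 71.6% and 90.9% with 11 of 145, and DESeq2 called 7 unchanged genes at 72 h. Raising the cholesterol list by 0.5 log2 units at 24 h called that list alone of 30 (adjusted p = 3.37e-63, adjusted p = 4.13e-05 with an estimated correlation). Genes were drawn independently of each other, so this could not show how often lists of correlated genes are called falsely.

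Alternatives to the test were pseudocounts of 0.5 and 5, no filter, a mean filter of 50 (13522 genes), TMM factors, equal column totals, no variance trend, replicate as a block, edgeR and DESeq2 on whole reads, a minimum change of 1 log2 unit, leaving out each library, and only the libraries of both time points. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.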

Results

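BMP4 drives human pluripotent stem cells away from self-renewal and towards trophoblast-like fates. Which genes respond, and in what order, is the question this time course addresses. H9 human embryonic stem cells were sampled before treatment and 8, 16, 24, 48 and 72 h after seeding on Matrigel in a KSR-based medium with 50 ng/ml BMP4. Each time point had 2 biological replicates, giving 12 libraries of total RNA. The labels name no untreated cells of the same age, so time, BMP4, the new medium and the new matrix changed together. The medium was changed every 24 h, so time since the last change differed between samples as well. Every change below is therefore a difference from the starting cells and cannot be assigned to BMP4 alone.

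The libraries differed widely in depth and in ribosomal RNA, the most abundant RNA of the cell. Between 20485149 (16 h replicate 1) and 201979931 reads (48 h replicate 2) were counted per library. Ribosomal RNA made up 21.5% of the reads in 16 h replicate 1 and 91.9% in 72 h replicate 1, and 95% Wilson intervals were at most 0.0356 points wide. Reads outside ribosomal RNA ranged from 9766719 (24 h replicate 1) to 52493197 (0 h replicate 1). Small noncoding RNAs took 18.7% and 19.9% of these reads in the 0 h replicates. Their share was 24.5% and 26.2% at 16 h, 25.6% and 25.5% at 24 h, and 17.0% and 17.1% at 72 h (intervals at most 0.0547 points wide).

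**Figure D1:**
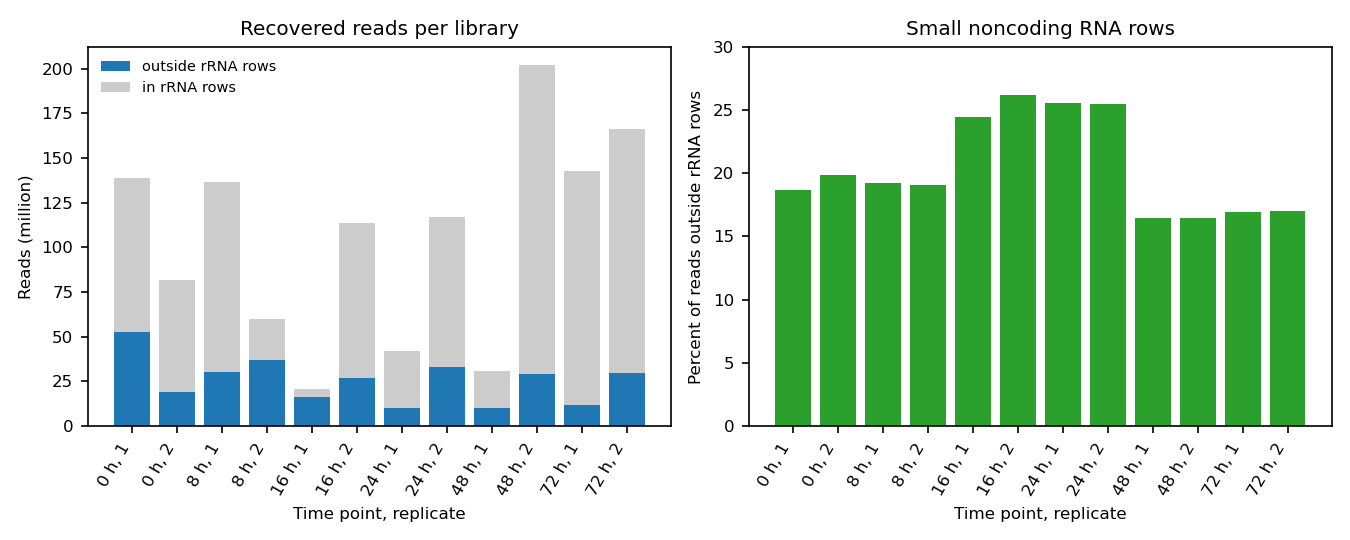
Reads inside and outside ribosomal RNA in each of the 12 libraries, and the percent of the reads outside ribosomal RNA that fell in small noncoding RNAs.

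Replicates resembled each other closely at all times, and the 48 h replicates least. Across genes, the log2 values of the replicates correlated with r = 0.994 at 0 h, 0.994 at 8 h, 0.991 at 16 h, 0.989 at 24 h, 0.980 at 48 h and 0.989 at 72 h. The median absolute difference between replicates was 0.0837 log2 units at 0 h and 0.218 at 48 h. In a principal component analysis the first component held 69.7% of the variance and followed time, and the next 2 components held 11.5% and 7.75%.

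Pluripotency factors did not decline together. POU5F1 (OCT4), which holds stem cells in the pluripotent state, stayed high through the first day and fell only later, whereas NANOG and SOX2, which act with it, were nearly gone by the third day. Normalized read counts of POU5F1 were 82062 ± 145 at 0 h, 97914 ± 3036 at 8 h, 94985 ± 10668 at 16 h, 89630.3 ± 5529 at 24 h, 48075 ± 5638 at 48 h and 11644 ± 1946 at 72 h (± values are SD, n = 2). It was not called changed at 8, 16 or 24 h (adjusted p = 0.221, 0.232 and 0.454). It fell at 48 h (log2 fold change -0.78, SE 0.13, adjusted p = 0.000236) and at 72 h (log2 fold change -2.83, SE 0.13, adjusted p = 2.12e-09). NANOG was 1535 ± 74.6 at 0 h, 1951 ± 2.03 at 8 h, 1372 ± 1.70 at 16 h, 669 ± 76.9 at 24 h, 27.4 ± 18.1 at 48 h and 8.99 ± 4.04 at 72 h. It was not called at 8 or 16 h (adjusted p = 0.571 and 0.75). NANOG fell at 24 h (log2 fold change -1.20, SE 0.35, adjusted p = 0.014), 48 h (log2 fold change -5.92, adjusted p = 3.22e-08) and 72 h (log2 fold change -7.32, adjusted p = 2.97e-09). The 24 h call of NANOG was lost without 0 h replicate 1 (adjusted p = 0.0517), 0 h replicate 2 (adjusted p = 0.0711) or 24 h replicate 2 (adjusted p = 0.0771). SOX2 was 3169 ± 41.6 at 0 h, 2259.8 ± 57.8 at 8 h, 2510.2 ± 172 at 16 h, 2572 ± 109 at 24 h, 241 ± 88.5 at 48 h and 46.9 ± 26.2 at 72 h. SOX2 was not called at 8, 16 or 24 h (adjusted p = 0.309, 0.394 and 0.429). With only the libraries of both time points SOX2 was called lower at each of these times, and POU5F1 and NANOG higher at 8 h. SOX2 fell at 48 h (log2 fold change -3.76, adjusted p = 3.89e-07) and 72 h (log2 fold change -6.16, adjusted p = 3.02e-09). TBXT (brachyury), a primitive streak marker, was 2.37 ± 0.0847 at 0 h, 0.92 ± 0.306 at 8 h, 1.36 ± 1.93 at 16 h, 2.61 ± 2.73 at 24 h, 4.84 ± 5.77 at 48 h and 0 at 72 h. These values lay below the level needed for testing.

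The transcription factors that install trophectoderm identity appeared within 8 h. All 6 factors below were called at the first sample, but CDX2 and HAND1 stayed low until 24 h. GATA2 was 0 at 0 h, 482 ± 17.4 at 8 h, 521 ± 31.9 at 16 h, 1176 ± 44.7 at 24 h, 2472 ± 231 at 48 h and 1967 ± 117 at 72 h. It was at least 537-fold higher at 8 h and at least 2190.1-fold at 72 h. GATA3 was 0.779 ± 0.529 at 0 h, 177 ± 6.32 at 8 h, 173 ± 7.84 at 16 h, 756 ± 10.8 at 24 h, 1711 ± 382 at 48 h and 1501 ± 306 at 72 h. The 8 h to 0 h comparison gave a ratio of 296 (95% counting interval 81.6 to 2453). TFAP2A was 0.606 ± 0.858 at 0 h, 112 ± 4.57 at 8 h, 243 ± 14.7 at 16 h, 922 ± 30.6 at 24 h, 1229 ± 111 at 48 h and 1344 ± 285 at 72 h. Its 8 h rise had a ratio of 125 (95% counting interval 42.3 to 607). TFAP2C was 14.8 ± 0.307 at 0 h, 182 ± 15.8 at 8 h, 124 ± 13.5 at 16 h, 686 ± 31.6 at 24 h, 2379 ± 24.7 at 48 h and 1633 ± 178 at 72 h. This factor was 12.3-fold higher at 8 h. CDX2 was 0 at 0 h, 5.31 ± 0.537 at 8 h, 4.81 ± 0.902 at 16 h, 48.1 ± 6.93 at 24 h, 347 ± 27.1 at 48 h and 111 ± 12.5 at 72 h. It was at least 5.91-fold higher at 8 h and at least 386-fold at 48 h. HAND1 was 0.202 ± 0.286 at 0 h, 8.49 ± 0.0584 at 8 h, 12.3 ± 3.88 at 16 h, 192 ± 8.23 at 24 h, 3522 ± 402 at 48 h and 4563 ± 134 at 72 h. The rise at 72 h had a ratio of 15387 (95% counting interval 2761 to 607826). Adjusted p for these 6 genes at 8 h ran from 1.78e-13 (GATA2) to 6.46e-05 (CDX2).

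The direct BMP response, the epithelial keratin and the placental hormone marked 3 different phases. ID1, a direct SMAD target, rose at once, KRT7 dipped before it climbed, and CGA, the alpha subunit of chorionic gonadotropin, appeared only on the third day. ID1 was 237 ± 14.1 at 0 h, 9933 ± 101 at 8 h, 6383 ± 864 at 16 h, 9500.4 ± 396 at 24 h, 7272 ± 442 at 48 h and 5213 ± 891 at 72 h. Its rise was 42.0-fold at 8 h (log2 fold change 5.39, SE 0.12, adjusted p = 2.5e-11). KRT7 was 113 ± 6.54 at 0 h, 87.9 ± 5.91 at 8 h, 42.6 ± 2.39 at 16 h, 162 ± 4.20 at 24 h, 4875 ± 1362 at 48 h and 8330.2 ± 3.10 at 72 h. It was not called at 8 h (adjusted p = 0.14). KRT7 fell at 16 h (log2 fold change -1.39, SE 0.15, adjusted p = 2.76e-05) and was higher than at the start at 24 h (log2 fold change 0.52, SE 0.15, adjusted p = 0.0147). It then rose 43.2-fold by 48 h and 73.7-fold by 72 h. The 24 h call was lost without 0 h replicate 1 (adjusted p = 0.0891) or 24 h replicate 2 (adjusted p = 0.0651). CGA was 0 at 0 h, 1.27 ± 0.191 at 8 h, 1.10 ± 0.373 at 16 h, 2.495 ± 0.314 at 24 h, 3.42 ± 1.68 at 48 h and 406 ± 28.1 at 72 h. It was not called at 8 or 16 h (adjusted p = 0.147 and 0.123), and at least 453-fold higher at 72 h (log2 fold change 8.67, SE 0.52, adjusted p = 1.8e-08). At 24 h CGA was called (adjusted p = 0.0121), but not without 0 h replicate 2 (adjusted p = 0.0505) or 24 h replicate 2 (adjusted p = 0.0503).

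**Figure D2:**
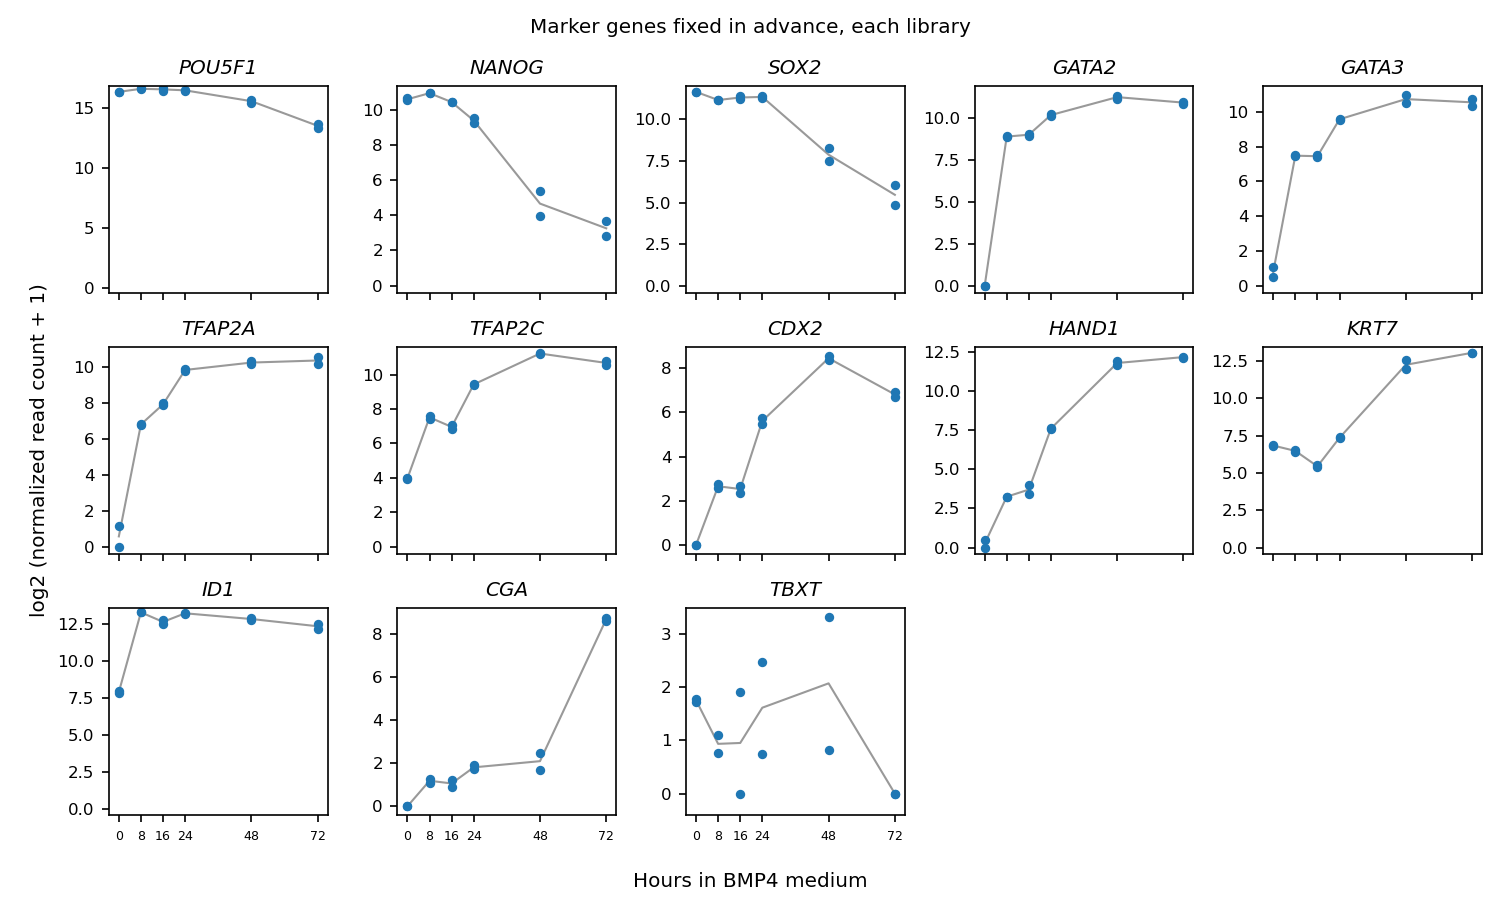
Normalized read counts of the 13 marker genes over 72 h on a log2 scale. Points are libraries and lines join the means of each time point.

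Calls against 0 h grew with every sample. Of 16147 genes tested, 2928 were called at 8 h, 6728 at 16 h, 8034 at 24 h, 10417 at 48 h and 11930 at 72 h (limma, Benjamini-Hochberg adjusted p < 0.05), and 14370 (89.0%) changed somewhere in the course by the moderated F test. The steps between samples gave 5794 (8 to 16 h), 4128 (16 to 24 h), 9045 (24 to 48 h) and 7421 (48 to 72 h) calls. These counts depend on which reads set the scaling. With all columns brought to 1 total, which includes ribosomal RNA, 87, 165, 261, 1346 and 3769 genes were called at 8, 16, 24, 48 and 72 h. With equal protein-coding totals, which leave ribosomal RNA out, 2872, 6671, 7891, 10516 and 12060 were called at these times.

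**Figure D3:**
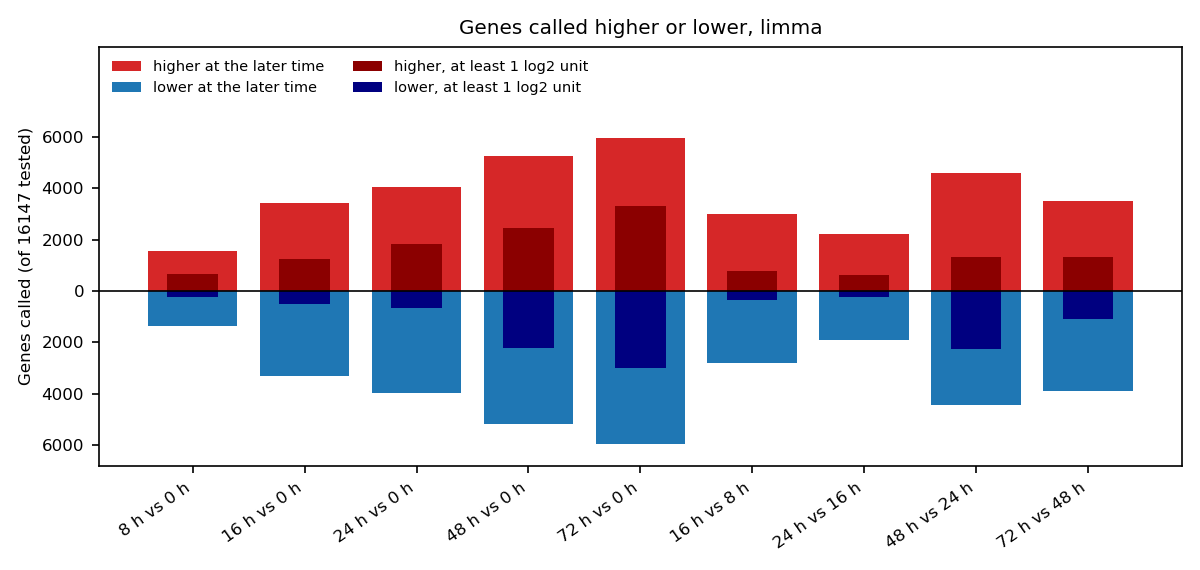
Genes called higher and lower in each of the 9 comparisons, with inner bars for changes of at least 1 log2 unit.

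**Figure D4:**
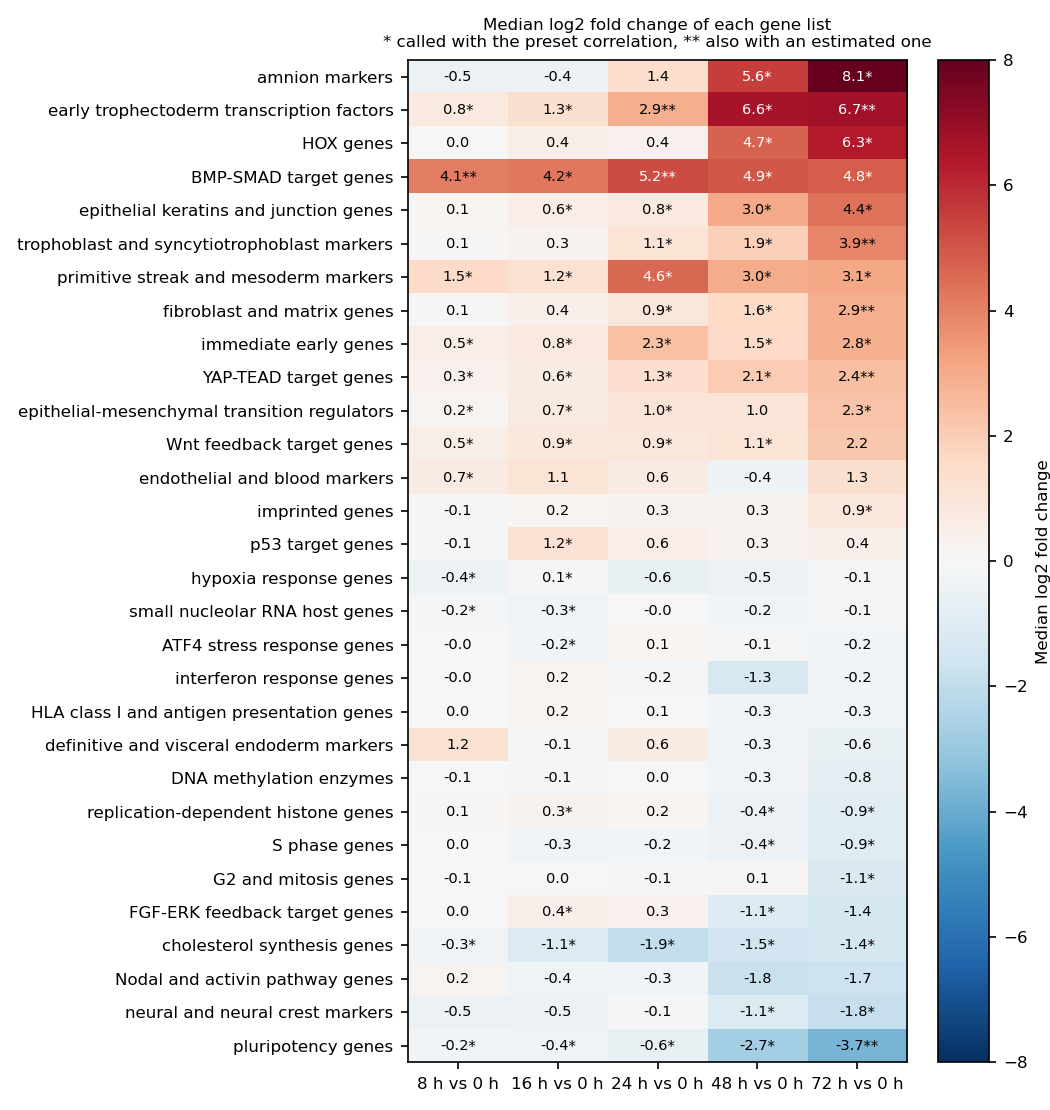
Median log2 fold change of each gene list against 0 h. One star marks a call with the preset correlation and 2 stars a call with an estimated correlation as well.

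SMAD target genes, the direct readout of BMP signalling, were already raised at 8 h, and trophectoderm factors were rising with them. Primitive streak and mesoderm markers that passed the mean filter were higher as a list in the same interval. TBXT did not pass that filter, which favours rises among members silent at the start. Part of the YAP-TEAD programme, which responds to cell shape and contact, was higher as well. Genes of cholesterol synthesis, which sterol supply represses, turned down. Among pluripotency genes a subset fell, while POU5F1, NANOG and SOX2 were not called. With only the libraries of both time points SOX2 was called lower, and POU5F1 and NANOG higher. Of the BMP-SMAD target genes, 18 rose and 0 fell of 18 tested. Examples were MSX2 from 1.38 ± 0.328 to 331 ± 0.881 (239-fold), GREM2 from 2.37 ± 0.0847 to 209 ± 19.7 (88.3-fold), NOG from 3.72 ± 1.26 to 269 ± 71.2 (72.4-fold) and SMAD6 from 11.9 ± 2.10 to 648 ± 78.8 (54.6-fold). The SMAD list stood at a median log2 fold change of 4.12 (adjusted p = 2.91e-36, adjusted p = 0.0109 with an estimated correlation). Of the early trophectoderm transcription factors, 16 rose and 0 fell of 24 tested (17 and 0 adjusted over the list alone), at a median log2 fold change of 0.79 (adjusted p = 2.56e-13, adjusted p = 0.0564 with an estimated correlation). Primitive streak and mesoderm markers gave 6 rises and 0 falls among 13 tested (7 and 1 adjusted over the list alone), at a median log2 fold change of 1.52 (adjusted p = 5.29e-05, adjusted p = 0.141 with an estimated correlation). Leading rises were WNT3 (59.1-fold), EOMES (66.0-fold), BMP4 (7.38-fold) and GATA5 (ratio 208, 95% counting interval 36.9 to 8258). For YAP-TEAD target genes, 8 rose and 2 fell of 18 tested (10 and 2 adjusted over the list alone), at a median log2 fold change of 0.35 (adjusted p = 0.000157, adjusted p = 0.141 with an estimated correlation). Examples were ANKRD1 from 2.37 ± 0.0847 to 62.2 ± 5.33 (26.3-fold), GADD45B (6.93-fold), CCN1 (2.97-fold) and DLC1 (2.76-fold). Pluripotency genes gave 2 rises and 10 falls among 27 tested (3 and 10 adjusted over the list alone), at a median log2 fold change of -0.20 (adjusted p = 0.00918, adjusted p = 0.273 with an estimated correlation). Those that fell included ZIC3 from 489 ± 32.9 to 61.6 ± 0.524 (7.93-fold), PRDM14 from 857 ± 40.4 to 270.2 ± 21.9 (3.17-fold) and ESRG from 1807 ± 1.35 to 637 ± 156 (2.84-fold). Cholesterol synthesis genes gave 0 rises and 11 falls among 25 tested, at a median log2 fold change of -0.29 (adjusted p = 7.04e-07, adjusted p = 0.259 with an estimated correlation). Here INSIG1 (3.27-fold), STARD4 (2.29-fold), LDLR (2.10-fold) and MVK (2.02-fold) fell most. All genes named here as changed at 8 h had an adjusted p of 0.000801 or lower.

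Other pathways moved only in part at 8 h. Wnt feedback target genes split, since NOTUM and LEF1 rose and AXIN2 fell. Hypoxia response genes also both rose and fell. Of the Wnt feedback target genes, 6 rose and 2 fell of 12 tested, at a median log2 fold change of 0.49 (adjusted p = 0.0233, adjusted p = 0.272 with an estimated correlation). Here NOTUM from 1.21 ± 1.72 to 276 ± 29.7 (227-fold) and LEF1 (7.18-fold) rose and AXIN2 (2.60-fold) fell. Of the hypoxia response genes, 4 rose and 10 fell of 19 tested, at a median log2 fold change of -0.44 (adjusted p = 0.0455, adjusted p = 0.668 with an estimated correlation). Here NDRG1 (5.08-fold), ADM (4.53-fold) and EGLN3 (4.03-fold) rose and SLC2A1 from 7389 ± 1043 to 2519 ± 172 (2.93-fold) fell. Epithelial-mesenchymal transition regulators gave 4 rises and 1 fall among 16 tested, at a median log2 fold change of 0.23 (adjusted p = 0.0167, adjusted p = 0.273 with an estimated correlation). Rises included SERPINE1 (6.98-fold), ITGA5 (3.47-fold) and MMP2 (2.74-fold). For immediate early genes, 6 rose and 1 fell of 14 tested, at a median log2 fold change of 0.54 (adjusted p = 0.0465, adjusted p = 0.722 with an estimated correlation). One of them was JUND (2.27-fold). Trophoblast markers were not called as a list, with 8 rises and 3 falls among 32 tested (9 and 4 adjusted over the list alone) and adjusted p = 0.0883, although PAPPA (5.48-fold) and PGF (3.73-fold) rose. The 6 largest rises of all were GATA2, GATA3, TFAP2A, NOTUM, MSX2 and the long noncoding RNA PCAT14 from 3.75 ± 0.413 to 868 ± 68.8 (231-fold). The largest falls included TMEM26 (9.33-fold), HES3 (9.31-fold), SORBS2 (7.37-fold) and STC1 (7.44-fold) besides ZIC3. Adjusted p was at most 0.000398 for these genes.

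The 8 h comparison called 2928 genes, 1574 higher and 1354 lower, and 891 changed by at least 1 log2 unit (645 and 246). It leaned on each of its 4 libraries. Without 0 h replicate 1 the count was 1533, without 0 h replicate 2 1441, without 8 h replicate 1 1674 and without 8 h replicate 2 1527. With equal column totals 86 were higher and 1 lower. With only the libraries of both time points 5820 genes were called, 2717 higher and 3103 lower. Hypoxia response genes lost their call without 0 h replicate 1 (adjusted p = 0.207) or 8 h replicate 2 (adjusted p = 0.105). Immediate early genes lost theirs without 0 h replicate 1 (adjusted p = 0.0709) or 8 h replicate 1 (adjusted p = 0.0535).

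At 16 h higher p53 target genes and lower sterol synthesis genes stood out. Activity of p53 itself was not measured. Genes that p53 activates to arrest growth, CDKN1A and BTG2 among them, climbed between 8 and 16 h. Sterol genes fell further, and transporters and enzymes under ATF4, which answers amino acid shortage, fell as well. Early trophectoderm and SMAD target genes stayed raised. Of the p53 target genes, 12 rose and 1 fell of 16 tested, at a median log2 fold change of 1.18 (adjusted p = 1.53e-06, adjusted p = 0.173 with an estimated correlation). Leading rises were BTG2 from 31.5 ± 1.10 to 319 ± 14.5 (10.1-fold), CDKN1A from 71.3 ± 1.44 to 309 ± 24.7 (4.33-fold), TP53INP1 (4.47-fold) and PHLDA3 (3.45-fold). Of the cholesterol synthesis genes, 0 rose and 21 fell of 25 tested (0 and 22 adjusted over the list alone), at a median log2 fold change of -1.12 (adjusted p = 1.31e-14, adjusted p = 0.121 with an estimated correlation). Falls included MVK from 621 ± 4.40 to 131 ± 20.8 (4.76-fold), INSIG1 (4.28-fold), HMGCS1 (3.64-fold) and SQLE (3.57-fold). ATF4 stress response genes gave 2 rises and 7 falls among 16 tested (2 and 8 adjusted over the list alone), at a median log2 fold change of -0.25 (adjusted p = 0.0407, adjusted p = 0.261 with an estimated correlation). Here SLC7A5 from 4619 ± 195 to 1189 ± 12.9 (3.89-fold), SLC7A11 (3.47-fold), TRIB3 (3.41-fold) and PSAT1 (2.53-fold) fell. Of the early trophectoderm transcription factors, 18 rose and 1 fell of 24 tested, at a median log2 fold change of 1.29 (adjusted p = 2.29e-09, adjusted p = 0.121 with an estimated correlation). Joining them was TBX3 from 0.404 ± 0.572 to 68.4 ± 9.30 (ratio 112, 95% counting interval 30.3 to 931). BMP-SMAD target genes gave 17 rises and 0 falls among 18 tested (18 and 0 adjusted over the list alone), at a median log2 fold change of 4.19 (adjusted p = 2.22e-20, adjusted p = 0.0508 with an estimated correlation). For pluripotency genes, 2 rose and 13 fell of 27 tested, at a median log2 fold change of -0.36 (adjusted p = 0.00181, adjusted p = 0.261 with an estimated correlation). Falls included ZIC3 (5.10-fold), ESRG (3.46-fold), PRDM14 (3.10-fold) and DNMT3B (2.31-fold). YAP-TEAD target genes gave 12 rises and 1 fall among 18 tested, at a median log2 fold change of 0.62 (adjusted p = 0.000127, adjusted p = 0.135 with an estimated correlation). Among them were ANKRD1 (26.8-fold) and DLC1 (4.55-fold). Each gene named as changed at 16 h had an adjusted p no higher than 0.00397.

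Junction, mesoderm and FGF-ERK feedback genes also moved at 16 h. Of the epithelial keratins and junction genes, 15 rose and 2 fell of 28 tested (16 and 2 adjusted over the list alone), at a median log2 fold change of 0.56 (adjusted p = 0.0153, adjusted p = 0.564 with an estimated correlation). Rises included ITGB4 from 35.4 ± 2.08 to 94.2 ± 6.08 (2.66-fold), CLDN4 (2.45-fold) and PKP3 (2.04-fold). Mesoderm markers gave 6 rises and 3 falls among 13 tested (7 and 3 adjusted over the list alone), at a median log2 fold change of 1.25 (adjusted p = 0.0258, adjusted p = 0.261 with an estimated correlation). Largest were EOMES from 1.18 ± 0.0423 to 198 ± 6.58 (168-fold) and GATA5 (ratio 355, 95% counting interval 62.9 to 14071). FGF-ERK feedback target genes, which track ERK activity, gave 9 rises and 1 fall among 16 tested, at a median log2 fold change of 0.43 (adjusted p = 0.0118, adjusted p = 0.261 with an estimated correlation). Leading members were EGR1 from 23.1 ± 5.01 to 79.1 ± 11.5 (3.42-fold), IER3 (2.87-fold) and DUSP6 (2.48-fold). Immediate early genes gave 8 rises and 1 fall among 14 tested, at a median log2 fold change of 0.76 (adjusted p = 0.0228, adjusted p = 0.564 with an estimated correlation). Here JUND (2.35-fold) and JUN (2.36-fold) rose. For epithelial-mesenchymal transition regulators, 7 rose and 0 fell of 16 tested (9 and 0 adjusted over the list alone), at a median log2 fold change of 0.70 (adjusted p = 0.00533, adjusted p = 0.261 with an estimated correlation). The list included SERPINE1 (3.84-fold), MMP2 (3.36-fold) and ITGA5 (3.23-fold). Wnt feedback target genes gave 6 rises and 3 falls among 12 tested, at a median log2 fold change of 0.85 (adjusted p = 0.0404, adjusted p = 0.261 with an estimated correlation). This list lost its call without 16 h replicate 1 (adjusted p = 0.0591). Hypoxia response genes gave 8 rises and 3 falls among 19 tested, at a median log2 fold change of 0.08 (adjusted p = 0.044, adjusted p = 0.564 with an estimated correlation). They included NDRG1 (7.62-fold), ADM (5.005-fold), EGLN3 (3.88-fold) and P4HA2 (3.27-fold). The hypoxia call was lost without 0 h replicate 2 (adjusted p = 0.106) or 16 h replicate 1 (adjusted p = 0.0786), and the ATF4 call without 0 h replicate 1 (adjusted p = 0.0636). Adjusted p reached at most 0.00184 among the genes named.

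The step from 8 to 16 h called 5794 genes, 2990 higher and 2804 lower. Only 3 lists were called in this step: p53 target genes (13 rose and 1 fell of 16, 14 and 1 adjusted over the list alone, median 1.39, adjusted p = 1.16e-08, adjusted p = 0.374 with an estimated correlation), hypoxia response genes (13 rose and 0 fell of 19, 14 and 0 adjusted over the list alone, median 0.58, adjusted p = 9.35e-06, adjusted p = 0.519 with an estimated correlation) and cholesterol synthesis genes (0 rose and 19 fell of 25, 0 and 21 adjusted over the list alone, median -0.72, adjusted p = 4.76e-10, adjusted p = 0.374 with an estimated correlation). SLC2A1, the glucose transporter, swung up and then down, from 2519 ± 172 at 8 h to 7497 ± 1019 at 16 h (2.98-fold) and 1613 ± 176 at 24 h. Largest rises were SLC1A1 from 19.4 ± 3.37 to 376 ± 12.9 (19.4-fold), LMOD1 (8.83-fold), CDKN1A (8.40-fold) and RBMS3 (8.57-fold). Falls included HMOX1 from 856 ± 81.7 to 123 ± 17.6 (6.97-fold), FAM24B-CUZD1 (7.60-fold) and MYOCD (6.31-fold). Adjusted p was 0.00189 or less for each of these. The count was 3792 without 8 h replicate 1, 3517 without 8 h replicate 2, 3607 without 16 h replicate 1, and 3 with equal column totals (2 higher, 1 lower). Against 0 h, 6728 genes were called (3412 higher, 3316 lower), 1742 of them by at least 1 log2 unit. Without 0 h replicate 2 this count was 4423, and with equal column totals 160 were higher and 5 lower.

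At 24 h the trophectoderm programme deepened and trophoblast markers were higher as a list. The cells' own BMP4 transcript rose steeply, and immediate early genes, which answer serum, stretch or growth factors, surged. Such a surge cannot be told apart from an effect of time since the last medium change. Matrix genes began to rise, whereas sterol genes reached their lowest level as a list. Of the early trophectoderm transcription factors, 22 rose and 0 fell of 24 tested, at a median log2 fold change of 2.91, or 2.90 with groups at 0 set to the floor (adjusted p = 5.1e-16, adjusted p = 0.0364 with an estimated correlation). Beside the GATA and AP-2 genes stood TBX3 from 0.404 ± 0.572 to 571 ± 39.0 (ratio 979, 95% counting interval 270.3 to 8091). BMP-SMAD target genes gave 18 rises and 0 falls among 18 tested, at a median log2 fold change of 5.23 (adjusted p = 6.4e-19, adjusted p = 0.0364 with an estimated correlation). Examples included MSX2 from 1.38 ± 0.328 to 1802 ± 52.9 (1301-fold), DLX5 (at least 227-fold) and NOG (243-fold). Of the trophoblast and syncytiotrophoblast markers, 14 rose and 4 fell of 32 tested, at a median log2 fold change of 1.10, or 1.12 with groups at 0 set to the floor (adjusted p = 0.00902, adjusted p = 0.13 with an estimated correlation). Here SLC40A1 from 0.202 ± 0.286 to 68.5 ± 26.1 (ratio 262, 95% counting interval 46.3 to 10422), NR2F2 (77.0-fold) and TACSTD2 (9.19-fold) rose. Primitive streak and mesoderm markers gave 10 rises and 2 falls among 13 tested, at a median log2 fold change of 4.61 (adjusted p = 0.000484, adjusted p = 0.13 with an estimated correlation). Prominent were BMP4 from 7.19 ± 5.27 to 1855 ± 86.8 (258-fold), TWIST1 (94.6-fold), EOMES (249-fold) and GATA5 (ratio 477, 95% counting interval 84.9 to 18912). For immediate early genes, 13 rose and 0 fell of 14 tested, at a median log2 fold change of 2.32 (adjusted p = 9.84e-07, adjusted p = 0.261 with an estimated correlation). Examples were EGR1 from 23.1 ± 5.01 to 847 ± 119.6 (36.6-fold), KLF4 (19.8-fold), FOS (12.4-fold) and FOSB (10.4-fold). Of the YAP-TEAD target genes, 13 rose and 0 fell of 18 tested, at a median log2 fold change of 1.35 (adjusted p = 4.82e-07, adjusted p = 0.0627 with an estimated correlation). Leading members were ANKRD1 (324-fold), DLC1 (26.0-fold), GADD45B (19.5-fold) and CCN1 (9.99-fold). No gene named as changed at 24 h had an adjusted p above 3.28e-05.

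Epithelial and matrix genes rose side by side at 24 h. Epithelial keratins and junction genes gave 19 rises and 1 fall among 28 tested (20 and 1 adjusted over the list alone), at a median log2 fold change of 0.80 (adjusted p = 0.000119, adjusted p = 0.417 with an estimated correlation). The list included CLDN4 from 225 ± 25.1 to 2032 ± 62.1 (9.02-fold), CLDN10 (6.73-fold), PKP2 (3.91-fold) and KRT8 (2.88-fold). Of the fibroblast and matrix genes, 10 rose and 1 fell of 15 tested, at a median log2 fold change of 0.93 (adjusted p = 0.00176, adjusted p = 0.0627 with an estimated correlation). Here FN1 from 948 ± 49.0 to 15543 ± 2787 (16.4-fold), POSTN (9.76-fold) and TAGLN (6.09-fold) rose and THY1 (3.604-fold) fell. Epithelial-mesenchymal transition regulators gave 10 rises and 0 falls among 16 tested, at a median log2 fold change of 1.02 (adjusted p = 0.000384, adjusted p = 0.159 with an estimated correlation). Wnt feedback target genes gave 7 rises and 1 fall among 12 tested (7 and 2 adjusted over the list alone), at a median log2 fold change of 0.92 (adjusted p = 0.00714, adjusted p = 0.18 with an estimated correlation). They included DKK1 (58.8-fold). Among pluripotency genes, 2 rose and 15 fell of 27 tested (2 and 17 adjusted over the list alone), at a median log2 fold change of -0.57 (adjusted p = 0.000466, adjusted p = 0.18 with an estimated correlation). Here USP44 (4.88-fold) and ESRG (4.23-fold) fell while FOXD3 from 297 ± 5.81 to 1598 ± 331 (5.39-fold) rose. Cholesterol synthesis genes gave 0 rises and 22 falls among 25 tested (0 and 23 adjusted over the list alone), at a median log2 fold change of -1.91 (adjusted p = 4.74e-16, adjusted p = 0.0627 with an estimated correlation). Falls included INSIG1 from 2635 ± 173 to 291 ± 22.6 (9.05-fold), SQLE (7.60-fold), HMGCS1 (7.10-fold) and PCSK9 (5.69-fold). Amnion markers were not called as a list (adjusted p = 0.0948), though 7 rose and 1 fell of 12 tested. One of the rises was ISL1 from 1.56 ± 1.06 to 297 ± 33.8 (191-fold). Besides 5 genes named above, PCAT14 (1065-fold) was among the 6 largest rises. The largest falls at 24 h were LINC00458 from 141 ± 26.8 to 2.84 ± 0.794 (49.8-fold), FAM24B-CUZD1 (37.0-fold), CUZD1 (34.7-fold), SORBS2 (27.1-fold), HES3 (27.8-fold) and TRIM54 (21.5-fold). All of these had an adjusted p of 0.00165 or lower.

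From 16 to 24 h, 4128 genes were called, 2213 higher and 1915 lower. With TMM factors the balance turned, with 2023 higher and 2194 lower. Of the lists, 15 were called. The 6 lists with the smallest adjusted p were early trophectoderm transcription factors (19 rose and 0 fell of 24, median 1.61, adjusted p = 1.31e-16, adjusted p = 0.0616 with an estimated correlation), cholesterol synthesis genes (0 rose and 18 fell of 25, median -0.74, adjusted p = 3.41e-11, adjusted p = 0.128 with an estimated correlation), BMP-SMAD target genes (15 rose and 0 fell of 18, median 0.81, adjusted p = 2.03e-08, adjusted p = 0.128 with an estimated correlation), immediate early genes (11 rose and 0 fell of 14, median 1.80, adjusted p = 5.6e-08, adjusted p = 0.27 with an estimated correlation), YAP-TEAD target genes (10 rose and 0 fell of 18, 12 and 0 adjusted over the list alone, median 0.72, adjusted p = 5.82e-08, adjusted p = 0.072 with an estimated correlation) and hypoxia response genes (2 rose and 13 fell of 19, median -0.80, adjusted p = 6.72e-07, adjusted p = 0.27 with an estimated correlation). Largest rises were ISL1 from 4.13 ± 0.0617 to 297 ± 33.8 (71.8-fold), NR2F2 (64.2-fold), BMP4 (50.2-fold) and TWIST1 (25.6-fold). Largest falls were D21S2088E from 320.3 ± 5.53 to 43.4 ± 6.78 (7.37-fold), SHISA2 (6.50-fold), NAV3 (5.66-fold) and VSNL1 (5.26-fold). Adjusted p was 0.00019 or lower. The step count was 2325 without 16 h replicate 1, 2733 without 16 h replicate 2, 2326 without 24 h replicate 1 and 6 with equal column totals (5 higher, 1 lower). Against 0 h, 8034 genes were called (4059 higher, 3975 lower), 2473 by at least 1 log2 unit, and with equal column totals 221 were higher and 40 lower.

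By 48 h most pluripotency genes had fallen and epithelial and amnion genes had risen. Counts, medians and folds in this paragraph are against 0 h. GABRP, VTCN1 and ISL1, which mark amnion, and TP63 and ENPEP, which mark cytotrophoblast, were all high at 48 h. Replicates at 48 h were the least alike (median difference 0.218 log2 units), and the SDs below are wide. Of the pluripotency genes, 1 rose and 24 fell of 27 tested, at a median log2 fold change of -2.73 (adjusted p = 7.82e-10, adjusted p = 0.0617 with an estimated correlation). Examples included FOXD3 from 297 ± 5.81 to 1.54 ± 2.17 (193-fold), ZIC2 (72.8-fold) and USP44 (52.6-fold). Of the epithelial keratins and junction genes, 26 rose and 0 fell of 28 tested, at a median log2 fold change of 3.01 (adjusted p = 1.55e-11, adjusted p = 0.16 with an estimated correlation). Prominent were KRT80 from 0.606 ± 0.858 to 189.8 ± 22.5 (ratio 220.1, 95% counting interval 74.7 to 1072), KRT23 (ratio 269, 95% counting interval 73.8 to 2232) and ITGB6 (at least 55.8-fold). Amnion markers gave 10 rises and 0 falls among 12 tested, at a median log2 fold change of 5.56, or 5.76 with groups at 0 set to the floor (adjusted p = 4.01e-05, adjusted p = 0.16 with an estimated correlation). Examples were GABRP from 106 ± 1.85 to 11198 ± 4845 (105-fold), ISL1 (1014-fold), WNT6 (ratio 2385, 95% counting interval 427 to 94283) and VTCN1 (194-fold). Of the trophoblast and syncytiotrophoblast markers, 23 rose and 4 fell of 32 tested, at a median log2 fold change of 1.91, or 1.89 with groups at 0 set to the floor (adjusted p = 0.00055, adjusted p = 0.0617 with an estimated correlation). Leading members were TP63 from 2.34 ± 1.59 to 695 ± 317 (297-fold), ENPEP (159.5-fold) and VGLL1 (at least 388-fold). Early trophectoderm transcription factors gave 23 rises and 1 fall among 24 tested, at a median log2 fold change of 6.61 (adjusted p = 1.61e-13, adjusted p = 0.0617 with an estimated correlation). TBX3 reached a ratio of 6465 (95% counting interval 1789 to 53392). BMP-SMAD target genes gave 18 rises and 0 falls among 18 tested, at a median log2 fold change of 4.95 (adjusted p = 2.05e-12, adjusted p = 0.0617 with an estimated correlation). For the YAP-TEAD target genes, 15 rose and 2 fell of 18 tested, at a median log2 fold change of 2.06 (adjusted p = 6.08e-06, adjusted p = 0.0617 with an estimated correlation). The list included ANKRD1 (767-fold) and DLC1 (115-fold). Named changes at 48 h had adjusted p up to 8.65e-06.

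Against 0 h, matrix genes were higher and FGF-ERK feedback, S phase and sterol genes lower at 48 h. Of the fibroblast and matrix genes, 9 rose and 3 fell of 15 tested, at a median log2 fold change of 1.57 (adjusted p = 0.0163, adjusted p = 0.136 with an estimated correlation). They included LUM from 0 to 732 ± 496 (at least 815-fold), FN1 (168-fold) and COL3A1 (54.1-fold). Mesoderm markers gave 11 rises and 2 falls among 13 tested, at a median log2 fold change of 2.996 (adjusted p = 0.00413, adjusted p = 0.16 with an estimated correlation). FGF-ERK feedback target genes had turned from higher to lower, with 5 rises and 11 falls among 16 tested, at a median log2 fold change of -1.05 (adjusted p = 0.0316, adjusted p = 0.32 with an estimated correlation). Here ETV1 from 2157 ± 21.2 to 234 ± 24.5 (9.23-fold), ETV4 (5.97-fold) and SPRY1 (6.40-fold) fell. Neural and neural crest markers gave 2 rises and 8 falls among 12 tested, at a median log2 fold change of -1.10 (adjusted p = 0.0286, adjusted p = 0.16 with an estimated correlation). Falls included HESX1 from 250.0 ± 0.244 to 5.65 ± 1.47 (44.3-fold) and OTX2 (13.7-fold). S phase genes gave 1 rise and 16 falls among 23 tested, at a median log2 fold change of -0.45 (adjusted p = 0.0091, adjusted p = 0.641 with an estimated correlation). Here RRM2 (1.80-fold), PCNA (1.74-fold) and MCM6 (1.66-fold) fell. Replication-dependent histone genes gave 0 rises and 36 falls among 65 tested (0 and 35 adjusted over the list alone), at a median log2 fold change of -0.45 (adjusted p = 4.01e-05, adjusted p = 0.641 with an estimated correlation). Most reduced was HIST1H1A from 204 ± 15.3 to 9.76 ± 5.12 (20.9-fold). Cholesterol synthesis genes gave 2 rises and 21 falls among 25 tested, at a median log2 fold change of -1.54 (adjusted p = 4.17e-08, adjusted p = 0.16 with an estimated correlation). The largest fall was PCSK9 from 1382 ± 3.24 to 21.6 ± 8.503 (63.9-fold). Wnt feedback target genes gave 6 rises and 1 fall among 12 tested, at a median log2 fold change of 1.10 (adjusted p = 0.0326, adjusted p = 0.226 with an estimated correlation). The call was lost without 48 h replicate 1 (adjusted p = 0.0566). Immediate early genes gave 9 rises and 2 falls among 14 tested, at a median log2 fold change of 1.51 (adjusted p = 0.0316, adjusted p = 0.635 with an estimated correlation). That call was lost without 48 h replicate 2 (adjusted p = 0.116). Here adjusted p was 0.000569 at most for a named gene.

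The step from 24 to 48 h called 9045 genes, 4590 higher and 4455 lower, and falls prevailed among changes of at least 1 log2 unit (1336 higher, 2243 lower). It called 10 lists, and the 6 with the smallest adjusted p were epithelial keratins and junction genes (23 rose and 0 fell of 28, 24 and 0 adjusted over the list alone, median 1.77, adjusted p = 2.06e-10, adjusted p = 0.26 with an estimated correlation), replication-dependent histone genes (0 rose and 55 fell of 65, 0 and 59 adjusted over the list alone, median -0.56, adjusted p = 2.45e-09, adjusted p = 0.539 with an estimated correlation), pluripotency genes (1 rose and 23 fell of 27, median -1.72, adjusted p = 6.22e-09, adjusted p = 0.164 with an estimated correlation), early trophectoderm transcription factors (18 rose and 1 fell of 24, median 1.41, adjusted p = 1.56e-07, adjusted p = 0.164 with an estimated correlation), FGF-ERK feedback target genes (2 rose and 13 fell of 16, median -1.35, adjusted p = 8.62e-05, adjusted p = 0.234 with an estimated correlation) and amnion markers (10 rose and 0 fell of 12, 10 and 1 adjusted over the list alone, median 3.47, adjusted p = 0.000356, adjusted p = 0.284 with an estimated correlation). Also called were the cholesterol synthesis genes (16 rose and 1 fell of 25, 17 and 1 adjusted over the list alone, median 0.34, adjusted p = 0.00242, adjusted p = 0.431 with an estimated correlation), which turned up again. Largest rises were GABRP from 12.4 ± 5.01 to 11198 ± 4845 (905-fold), EPAS1 (822-fold), LUM (ratio 1726, 95% counting interval 309 to 68227) and TRIM55 (ratio 636, 95% counting interval 217 to 3088). Largest falls were FOXD3 from 1598 ± 331 to 1.54 ± 2.17 (1041-fold), ZFP57 (at least 299.6-fold), HLA-DMB (70.0-fold) and TTLL6 (ratio 0.0129, 95% counting interval 0.00265 to 0.0383) (adjusted p at most 9.67e-06). Against 0 h, 10417 genes were called (5237 higher, 5180 lower), 4693 of them by at least 1 log2 unit. For that comparison equal column totals gave 571 higher and 775 lower, and equal protein-coding totals 4659 higher and 5857 lower. With equal column totals the step called 650 genes, 203 higher and 447 lower, and with equal protein-coding totals 9107, 3232 higher and 5875 lower.

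At 72 h trophoblast, amnion and matrix genes were higher as lists. PAPPA2, a placental protease, and CGA now stood beside keratins and integrins. Mesenchymal genes such as LUM and COL3A1 were among the largest rises, and cell cycle genes had fallen. One column of this time point is headed 71 h and was taken as 72 h replicate 1. Of the trophoblast and syncytiotrophoblast markers, 27 rose and 4 fell of 32 tested, at a median log2 fold change of 3.91 (adjusted p = 6.25e-06, adjusted p = 0.0448 with an estimated correlation). Examples were PAPPA2 from 13.4 ± 2.31 to 7583 ± 851 (568-fold), SLC40A1 (ratio 12610.3, 95% counting interval 2263 to 498153), VGLL1 (at least 1087-fold) and NR2F2 (665-fold). Early trophectoderm transcription factors gave 22 rises and 1 fall among 24 tested, at a median log2 fold change of 6.75, or 6.82 with groups at 0 set to the floor (adjusted p = 5.16e-11, adjusted p = 0.0448 with an estimated correlation). Leading members were MEIS1 from 3.32 ± 1.83 to 5209 ± 194 (1571-fold) and TBX3 (ratio 3938, 95% counting interval 1089 to 32525). Epithelial keratins and junction genes gave 25 rises and 2 falls among 28 tested, at a median log2 fold change of 4.36 (adjusted p = 1.82e-09, adjusted p = 0.141 with an estimated correlation). The list included KRT23 from 0.404 ± 0.572 to 707 ± 39.1 (ratio 1201, 95% counting interval 332 to 9927), KRT17 (231-fold) and ITGB6 (at least 654-fold). Amnion markers gave 12 rises and 0 falls among 12 tested, at a median log2 fold change of 8.08 (adjusted p = 4.51e-06, adjusted p = 0.122 with an estimated correlation). They included VTCN1 from 7.99 ± 5.01 to 8315 ± 445 (1041-fold), BNC1 (569-fold) and WNT6 (ratio 1932, 95% counting interval 346 to 76372). Of the fibroblast and matrix genes, 13 rose and 1 fell of 15 tested, at a median log2 fold change of 2.89 (adjusted p = 3.81e-06, adjusted p = 0.0448 with an estimated correlation). Examples included LUM from 0 to 17582 ± 2615 (at least 19582-fold), COL3A1 (2598-fold), DCN (at least 347-fold) and FN1 (250.0-fold). For pluripotency genes, 0 rose and 25 fell of 27 tested, at a median log2 fold change of -3.73 (adjusted p = 5.16e-11, adjusted p = 0.0448 with an estimated correlation). Prominent were TDGF1 from 8492 ± 79.6 to 11.6 ± 4.82 (733-fold), ZIC2 (343-fold), PRDM14 (388-fold) and FOXD3 (ratio 0.00193, 95% counting interval 4.89e-05 to 0.0108). YAP-TEAD target genes gave 16 rises and 2 falls among 18 tested, at a median log2 fold change of 2.4003 (adjusted p = 1.34e-06, adjusted p = 0.0489 with an estimated correlation). Largest was ANKRD1 (1464-fold). BMP-SMAD target genes gave 18 rises and 0 falls among 18 tested, at a median log2 fold change of 4.83 (adjusted p = 1.3e-09, adjusted p = 0.057 with an estimated correlation). The highest adjusted p of a gene named here as changed at 72 h was 2.85e-07.

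Growth and imprinted genes separated the 72 h cells further from the start. S phase genes gave 1 rise and 19 falls among 23 tested, at a median log2 fold change of -0.95 (adjusted p = 8.89e-05, adjusted p = 0.452 with an estimated correlation). Falls included MCM2 from 6143 ± 90.7 to 1773 ± 316 (3.47-fold) and RRM2 (3.16-fold). G2 and mitosis genes gave 0 rises and 23 falls among 24 tested, at a median log2 fold change of -1.13 (adjusted p = 1.67e-06, adjusted p = 0.415 with an estimated correlation). Leading members were BUB1B from 4027 ± 33.3 to 1049 ± 118 (3.84-fold), BUB1 (3.39-fold) and CCNA2 (2.98-fold). Histone genes gave 1 rise and 57 falls among 65 tested (1 and 58 adjusted over the list alone), at a median log2 fold change of -0.92 (adjusted p = 2.02e-08, adjusted p = 0.486 with an estimated correlation). Imprinted genes, several of which control placental growth, gave 15 rises and 5 falls among 23 tested, at a median log2 fold change of 0.87 (adjusted p = 0.031, adjusted p = 0.122 with an estimated correlation). Here H19 from 122 ± 16.2 to 69180.0 ± 1204 (566-fold), IGF2 (279.9-fold) and CDKN1C (39.7-fold) rose. Epithelial-mesenchymal transition regulators gave 13 rises and 2 falls among 16 tested, at a median log2 fold change of 2.26 (adjusted p = 0.00112, adjusted p = 0.146 with an estimated correlation). The list included SNAI2 from 10.2 ± 0.191 to 1562 ± 4.495 (152-fold), PRRX1 (41.2-fold) and VIM (8.14-fold). Mesoderm markers gave 10 rises and 1 fall among 13 tested, at a median log2 fold change of 3.11 (adjusted p = 0.00132, adjusted p = 0.122 with an estimated correlation). They included MSX1 (ratio 366, 95% counting interval 101 to 3036). Immediate early genes gave 12 rises and 0 falls among 14 tested, at a median log2 fold change of 2.82 (adjusted p = 0.000346, adjusted p = 0.39 with an estimated correlation). Examples included JUN (22.3-fold), EGR1 (16.4-fold) and KLF4 (16.1-fold). Neural markers gave 1 rise and 8 falls among 12 tested, at a median log2 fold change of -1.82 (adjusted p = 0.0103, adjusted p = 0.122 with an estimated correlation). Cholesterol synthesis genes gave 0 rises and 23 falls among 25 tested, at a median log2 fold change of -1.43 (adjusted p = 3.18e-08, adjusted p = 0.122 with an estimated correlation). The 6 largest rises were LUM, EPAS1 (11695-fold), HAND1 (ratio 15387, 95% counting interval 2761 to 607826), SLC40A1, COL3A1 and GATA2. The 6 largest falls were LCK from 1543 ± 75.4 to 0 (at least 903-fold), LINC00678 (ratio 0.000459, 95% counting interval 5.56e-05 to 0.00166), TDGF1, TDGF1P3 (872-fold), D21S2088E (at least 246-fold) and ZIC2. In this paragraph adjusted p did not exceed 2.05e-06.

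The step from 48 to 72 h called 7421 genes, 3511 higher and 3910 lower, and 14 of the lists were called. Smallest in adjusted p were G2 and mitosis genes (0 rose and 24 fell of 24, median -1.16, adjusted p = 1.21e-13, adjusted p = 0.404 with an estimated correlation), fibroblast and matrix genes (13 rose and 1 fell of 15, median 2.41, adjusted p = 3.75e-09, adjusted p = 0.0162 with an estimated correlation), pluripotency genes (1 rose and 22 fell of 27, 1 and 23 adjusted over the list alone, median -1.16 or -1.14 with groups at 0 set to the floor, adjusted p = 2.41e-09, adjusted p = 0.0837 with an estimated correlation), trophoblast and syncytiotrophoblast markers (21 rose and 3 fell of 32, 23 and 4 adjusted over the list alone, median 1.45, adjusted p = 2.39e-06, adjusted p = 0.0366 with an estimated correlation), replication-dependent histone genes (0 rose and 35 fell of 65, 1 and 35 adjusted over the list alone, median -0.45, adjusted p = 2.39e-06, adjusted p = 0.677 with an estimated correlation) and S phase genes (1 rose and 15 fell of 23, 1 and 18 adjusted over the list alone, median -0.47, adjusted p = 0.000204, adjusted p = 0.584 with an estimated correlation). Largest rises were DCN from 0.384 ± 0.543 to 312 ± 50.4 (ratio 573, 95% counting interval 103 to 22691), STMN2 (209-fold), NDNF (95.9-fold) and PLSCR5 (219.5-fold). Largest falls were DCLK1 from 1605 ± 992 to 47.5 ± 6.48 (33.8-fold), CRLF1 (27.9-fold), SEMA3E (24.8-fold) and ANGPT1 (21.1-fold). Placental genes with large rises in this step were CGA from 3.42 ± 1.68 to 406 ± 28.1 (119-fold), PGF (19.6-fold), ERVV-1 (21.5-fold) and PAPPA2 (19.3-fold). Adjusted p was 0.000692 or less for all genes of this step, but PLSCR5 lost its call with DESeq2. With equal column totals it called 176 genes, 63 higher and 113 lower. Only the libraries of both time points gave 4511 genes, 2337 higher and 2174 lower. Equal protein-coding totals gave 7705, 2893 higher and 4812 lower. Against 0 h, 11930 genes were called (5956 higher, 5974 lower), 6303 by at least 1 log2 unit, and with equal column totals 646 were higher and 3123 lower. For that comparison equal protein-coding totals gave 5033 higher and 7027 lower.

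Some genes rose early and were lost again by 72 h, among them HHEX and EOMES. These 2 genes, which specify endoderm and mesoderm, peaked within the first day and returned close to their starting level. Genes higher at 8 h than at 0 h and lower at 72 h than at 8 h numbered 576, and the same pattern around 16 and 24 h was met by 1295 and 1372. Independent rises and falls would give 574, 1192 and 1377, so the 8 and 24 h counts were close to those of independence. Unchanged simulated groups gave 0. No gene changed at any time in that simulation, so it could not show how many such calls arise when many genes change. HHEX was 1.59 ± 0.614 at 0 h, 168 ± 3.16 at 8 h, 189.6 ± 28.5 at 16 h and 1.42 ± 0.888 at 72 h. EOMES was 1.18 ± 0.0423 at 0 h, 198 ± 6.58 at 16 h, 295 ± 14.7 at 24 h and 3.86 ± 3.22 at 72 h. COCH was 249 ± 3.92 at 0 h, 5847 ± 123 at 24 h and 141 ± 0.415 at 72 h, and CBLN1 was 24.96 ± 7.58 at 0 h, 626 ± 14.0 at 8 h and 4.02 ± 0.101 at 72 h. GREM1, a secreted BMP antagonist, went from 22.6 ± 0.582 to 1149 ± 128 at 8 h and 58.6 ± 7.62 at 72 h. CRLF1 (20.9 ± 0.191, 564 ± 48.6 and 9.38 ± 4.59 at 0, 24 and 72 h) and GRIK3 (65.7 ± 4.89, 1493 ± 134 and 36.7 ± 2.77) peaked at 24 h. The 8 h count was 345 without 0 h replicate 1, 318 without 0 h replicate 2, 353 without 8 h replicate 1 and 311 without 8 h replicate 2. The 16 h count was 854 without 16 h replicate 1. With equal column totals the 3 counts were 42, 75 and 74.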

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

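Counts moved by more than 1.5-fold with scaling by column totals, a size of change asked for, fits to only the libraries of both time points and an estimated correlation within lists. They also did so without single libraries of 0, 8, 16 and 24 h. Of 420 counts under alternatives 371 stayed within 1.5-fold and 49 moved further. Pseudocounts, filters, TMM factors, no variance trend, edgeR and DESeq2 moved none of the counts that far.

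With equal column totals the gene counts were 87, 165, 261, 1346 and 3769 against 0 h (8 to 72 h), 3, 6, 650 and 176 in the 4 steps, 3808 over the course, and 42, 75 and 74 for transient genes. Column totals include ribosomal RNA (21.5% to 91.9% of reads). With equal protein-coding totals, which leave it out, 2872, 6671, 7891, 10516 and 12060 genes were called against 0 h. The drop therefore came from reads outside protein-coding genes, and ribosomal RNA was not tested alone. Scaling to equal column totals moved the median of all genes by -1.41 log2 units at 72 h, against -0.0166 with TMM factors and -0.174 with equal protein-coding totals. It also turned the sign of 3 uncalled changes, to 0.335 for NANOG at 16 h, 0.159 for SOX2 at 16 h and -0.131 for POU5F1 at 24 h. With this scaling the median of all genes was 0.491 at 16 h and -0.253 at 24 h. These turns reflect that shared shift and say nothing about the 3 genes.

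With at least 1 log2 unit asked for, 891, 1742, 2473, 4693 and 6303 genes were called against 0 h, 1109, 885, 3579 and 2378 in the steps, 7602 over the course and 211, 416 and 537 as transient. Only the libraries of both time points gave 5820 genes at 8 h and 4511 from 48 to 72 h. An estimated correlation left 1, 0, 2, 0 and 5 lists of 12, 16, 12, 17 and 18 at 8, 16, 24, 48 and 72 h. Whether depth limited the calling of small changes was not tested. The shallowest library, 24 h replicate 1, held 9766719 reads outside ribosomal RNA.

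Leaving out each library in turn gave 1441 to 3956, 4423 to 7732, 5890 to 8935, 8820 to 10480 and 10670 to 12338 genes against 0 h, 3517 to 6990, 2325 to 5318, 7452 to 9106 and 5847 to 8178 in the steps, 13768 to 14640 over the course and 311 to 754, 854 to 1532 and 989 to 1551 as transient. When 1 library of a time point was left out, the other was assumed to vary like the rest. With replicate as a block 2849, 6661, 7993, 10365 and 11894 genes were called at 8, 16, 24, 48 and 72 h, and the hypoxia list lost its 16 h call (adjusted p = 0.0503). Immediate early genes lost their 8 h call with TMM factors (adjusted p = 0.0507). Called lists at 24 and 72 h kept their call under all 16 other settings run for lists (12 left-out libraries, pseudocount 5, TMM factors, replicate block and equal protein-coding totals). Replicate numbers did not pair the libraries, since the 15 correlations of replicate differences between time points ran from -0.0935 to 0.128.

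Named genes in 280 gene comparisons gave 6932 values under 25 settings, since a filter at a mean of 50 and the loss of both 48 h libraries left some out. The settings at least 1 log2 unit and estimated correlation were not run for single genes. The call and sign were kept in 6806, a call was lost in 112, gained in 11 and the sign turned in 3. Members whose call was lost without 1 library had been left out of the text. Stability under left-out libraries was thus partly fixed by that choice and lends the named genes little support. Equal column totals made 105 of these differences. PLSCR5 lost its call from 48 to 72 h with DESeq2, and SOX2 was called lower at 8, 16 and 24 h with only the libraries of both time points. With those libraries alone POU5F1 and NANOG were called higher at 8 h, which DESeq2 also called for NANOG. KRT7 at 8 h was called lower without either 48 h library, and CGA was called at 8 and 16 h with no variance trend. Settings added after the data were seen were equal protein-coding totals, with 12060 genes called at 72 h, and leaving out both 48 h libraries, with 12335. Equal protein-coding totals ended the call of immediate early genes at 8 h (adjusted p = 0.0691). They also ended the 16 h calls of Wnt feedback target genes (adjusted p = 0.0619), hypoxia response genes (adjusted p = 0.0537) and small nucleolar RNA host genes (adjusted p = 0.0552). With both 48 h libraries left out 3955 genes were called at 8 h.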

Other observations

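The remaining lists were called at few times or at none. Of the HOX genes, largely silent in stem cells, the 5 that passed the mean filter came on late. A gene silent at the start passed that filter only by rising later. The direction of these changes was thus largely fixed by the filter, and the list calls carry little weight. At 48 h 4 rose and 0 fell of 5 tested, at a median log2 fold change of 4.69, or 4.82 with groups at 0 set to the floor (adjusted p = 0.0238, adjusted p = 0.191 with an estimated correlation). At 72 h 5 rose and 0 fell of 5 tested, at a median log2 fold change of 6.32, or 6.46 with groups at 0 set to the floor (adjusted p = 0.0103, adjusted p = 0.152 with an estimated correlation), and examples were HOXB2 from 0 to 319.7 ± 21.2 (at least 356-fold) and HOXA1 (at least 100.2-fold). Small nucleolar RNA host genes were lower as a list at 8 h, when 0 rose and 4 fell of 19 tested, at a median log2 fold change of -0.18 (adjusted p = 0.0233, adjusted p = 0.526 with an estimated correlation), and at 16 h, when 1 rose and 3 fell of 19 tested, at a median log2 fold change of -0.27 (adjusted p = 0.0449, adjusted p = 0.564 with an estimated correlation). Those calls were lost without 0 h replicate 2 (adjusted p = 0.0552 at 8 h and 0.106 at 16 h), and at 16 h without 16 h replicate 1 (adjusted p = 0.157). At 72 h no call was made for small nucleolar RNA host genes (5 rose and 6 fell of 19, adjusted p = 0.606), although SNHG4 from 470.1 ± 31.4 to 61.1 ± 0.399 (7.70-fold) fell and SNHG18 (6.86-fold) rose. Endothelial and blood markers were called at 8 h, when 1 rose and 0 fell of 5 tested (2 and 0 adjusted over the list alone), at a median log2 fold change of 0.65 (adjusted p = 0.0401, adjusted p = 0.259 with an estimated correlation). The call was lost without 0 h replicate 1 (adjusted p = 0.143) or 8 h replicate 1 (adjusted p = 0.0547). Histone genes were higher at 16 h, when 19 rose and 1 fell of 65 tested (8 and 0 adjusted over the list alone), at a median log2 fold change of 0.27 (adjusted p = 0.00198, adjusted p = 0.662 with an estimated correlation), before the falls at 48 and 72 h.

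At 72 h 11 more lists gained no call, although single members changed strongly. These were definitive and visceral endoderm markers (2 rose and 3 fell of 6, adjusted p = 0.828), endothelial and blood markers (3 rose and 2 fell of 5, adjusted p = 0.747), Nodal and activin pathway genes (4 rose and 8 fell of 13, adjusted p = 0.269), DNA methylation enzymes (1 rose and 6 fell of 9, 2 and 6 adjusted over the list alone, adjusted p = 0.122), interferon response genes (4 rose and 8 fell of 15, adjusted p = 0.342), HLA class I and antigen presentation genes (5 rose and 7 fell of 14, adjusted p = 0.606), Wnt feedback target genes (7 rose and 2 fell of 12, adjusted p = 0.12), FGF-ERK feedback target genes (6 rose and 10 fell of 16, adjusted p = 0.2), p53 target genes (9 rose and 5 fell of 16, 9 and 6 adjusted over the list alone, adjusted p = 0.342), ATF4 stress response genes (5 rose and 8 fell of 16, adjusted p = 0.558) and hypoxia response genes (7 rose and 8 fell of 19, 8 and 8 adjusted over the list alone, adjusted p = 0.9). Among endoderm markers GATA6 from 0.202 ± 0.286 to 102 ± 29.2 (ratio 373, 95% counting interval 66.2 to 14808) and CXCR4 (9.45-fold) rose and FOXA3 (6.95-fold) fell, and among blood and vessel markers RUNX1 (94.2-fold) and CDH5 (11.9-fold) rose. Nodal pathway genes GDF3 (at least 71.6-fold) and INHBE (ratio 0.00276, 95% counting interval 6.98e-05 to 0.0154) fell and SMAD3 (7.42-fold) rose. TET2 from 76.9 ± 6.10 to 743 ± 22.4 (9.66-fold) rose and DNMT3B from 25883 ± 35.4 to 3626 ± 639 (7.14-fold) fell. Interferon response genes BST2 (31.8-fold), MX1 (10.6-fold) and IFITM1 (5.96-fold) fell and IFI6 (9.98-fold) rose, and the immunoproteasome genes PSMB9 (13.4-fold) and PSMB8 (7.36-fold) fell with HLA-F (4.46-fold). Under ATF4, PSAT1 (20.99-fold) and ASNS (9.45-fold) fell and ATF3 (7.61-fold) rose. Every gene named here as changed had an adjusted p of 2.82e-05 or lower. Mitochondrially encoded mRNAs were not analysed here.

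Explanations for 3 patterns were tested, and all but 2 of the tests (the depth test and the fibroblast test below) were chosen after the pattern was seen. The first pattern is that 48 h replicate 2 lay further along the way from 24 h to 72 h than replicate 1, at positions 0.679 and 0.540. Drawing replicate 2 down to the depth of replicate 1 left 106.5% of the gap (20 draws), so lower depth was excluded. Replicate 2 lay ahead at 2 of the 3 time points 8, 16 and 24 h, by gaps of 0.0067, -0.0208 and 0.0132, which speaks against a steady delay in collection. In 13 genes nearly absent at 24 h and in 48 h replicate 1, replicate 2 covered 1.34% of the difference between replicate 1 and 72 h (median). In 497 genes already present in replicate 1 it covered 21.5%, a ratio of 0.0623, and a mixture with 72 h RNA would give equal shares. A faster course in replicate 2 could explain the gap, and was not tested.

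The second pattern is the rise of matrix genes at 72 h, when COL1A2 was 14961 ± 1362, COL1A1 3317 ± 475 and LUM 17582 ± 2615 (SD, n = 2). Cultured fibroblasts make far more type I collagen than lumican, whereas COL1A1 lay 5.30-fold below LUM, against that source. The ratio of COL1A2 to LUM was 0.851, not under the bound of 0.5 set for both genes, so carry-over of fibroblasts stayed undecided. Another possible source is mesenchymal cells arising in the culture, and 5 mesenchyme regulators had a median log2 fold change of 3.11. The 5 were TWIST1 (3.11), PRRX1 (4.82), PDGFRA (1.22), SNAI2 (7.12) and TWIST2 (-0.79, not called). FOXF1 was chosen too, but its mean was below 10 and it was not tested. Fibroblasts express such genes too, so the 2 sources could not be told apart. Some of these genes are also in the mesoderm and transition lists, so the test is not independent of those calls.

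The third pattern is the larger share of small noncoding RNAs at 16 and 24 h. The 16 h replicates differed by 1.70 points in this share although ribosomal RNA made up 21.5% of 1 and 76.3% of the other, against a rise of 6.16 points from 8 to 16 h. Carry-over of ribosomal RNA was therefore excluded. Better recovery of all small RNAs could raise the share, and would shift each abundant small RNA alike. Over 38 abundant small RNA genes, 29 of which had a positive change, the median log2 change was 0.45, with an interquartile range of 0.247. These changes were not tested gene by gene. The other 9 had negative changes, the smallest -0.0108 (SNORA33). Among them were 4 SNAR genes with changes of -0.996 to -1.16 log2 units, which a shared gain does not account for. For the genes with positive changes the explanation stayed open.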
